A study of Mus musculus with 2 samples.

How the data were processed

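Gene expression was measured by RNA sequencing in 2 samples of mouse trophoblast stem cells, 1 differentiated for 2 days without doxycycline and 1 for the same time with 0.6 µg/ml doxycycline to induce Hand1. Groups were taken from the treatment given in the labels, and the 2 expression columns of the deposited table were matched to the samples by their names. Libraries were sequenced on a BGISEQ-500, per the labels. Alignment to mm10 with HISAT2 and counting of reads per gene with edgeR are stated in the series' design text, whereas TopHat and edgeR are named in the submitters' processing notes, so the aligner is not settled. Versions, the gene annotation and the use of strand in counting are not given in the sources used here.

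The design text speaks of raw counts, but the deposited expression values are not whole numbers, and their unit is not stated in the file. They were read as RPKM from the values. The columns summed to 436150 and 433673, and for low genes with a single annotated transcript the deposited RPKM times transcript length in kilobases fell near whole multiples of a common step: 76.3% of 759 no-dox values and 77.5% of 717 dox values lay within 0.1 of a whole multiple, against 20% by chance. The step itself was the median of 322 no-dox and 314 dox values that are also among those checked, so 20% is too low a yardstick. This step gave an estimated depth of 20000000 counted reads without and 19200000 with doxycycline, a difference of 3.79%. Reads per gene were estimated as RPKM times transcript length times this depth; since the authors' gene lengths are not given in the sources used here, these reads are approximate and served only for counting intervals and for describing depth.

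The deposited table also holds a fold and a p-value per gene from the authors. The deposited fold was found to be close to the no-dox value over the dox value with 0.125 added to both. A fold below 1 is thus a higher value with doxycycline. The deposited p-value was compared with a negative binomial exact test on slightly rescaled RPKM values, rounded to whole numbers, as described in the closing observations. Both columns are reported as the authors' own values and compared with the values computed here, and neither entered a ratio, count of genes or list median. Symbols of 26 rows altered to dates in the table's row names were taken from its second symbol column.

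The plan fixed before the data were examined was written for read counts. Because the values were RPKM, its fallback for normalized units was used: log2 of (dox RPKM + 1) over (no-dox RPKM + 1), with no test, no p-value and no replicate error, since each group holds 1 library. This scale understates the ratio of low genes. Genes with at least 1 RPKM in one library were eligible (11671 genes), and a gene was counted as higher or lower when the log2 ratio was at least 1 in size. Plain folds, where given, are ratios of RPKM without the pseudocount. Counting intervals are exact conditional binomial 95% intervals of the plain ratio from estimated reads, and cover counting error only.

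Genes were named by a rule fixed in advance. It took Hand1 and Adgrg1 whatever their values, up to 15 higher and 15 lower genes past 2-fold with a mean of at least 5 RPKM, and, from each of 46 gene lists also fixed in advance, up to 4 members past 2-fold and up to 2 other members with the highest mean level. Any other gene is marked as chosen after its values were seen. Of 877 list symbols 862 were found in the table, 2 of them under an older symbol. For each of the 40 lists with at least 3 eligible members the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean level, and the percentile is given. In a second draw each level bin was split into 5 bins of transcript length, and in another draw into 5 bins of GC content. Lengths, GC content and coordinates came from GENCODE M21 on GRCm38, the assembly named mm10, except that small nucleolar and Cajal body RNAs took RefSeq lengths where listed. Length and GC content from GENCODE were medians over a gene's basic transcripts, and 96.6% of eligible genes had a length.

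Alternatives planned in advance were scaling by column total, median of ratios and upper quartile, a pseudocount of 0.1, no minimum or a minimum of 5 RPKM, thresholds of 1.5-fold and 4-fold, a counting interval bound of 2-fold, and leaving out predicted gene models. Those added after the data were seen were a trimmed mean of log ratios, removal of a running median over transcript length or GC content (window 501 genes), a counting interval that excludes no difference, leaving out small nucleolar and Cajal body RNAs, and the random lists matched on length or GC content.

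The scripts were tested on simulated libraries for the comparison of dox with no dox, drawn for 22197 genes at the estimated depths. Of genes changed 3-fold or 4-fold 100% passed the 2-fold rule, of genes changed 1.5-fold 0% did, and 14 of 11015 unchanged genes passed it. A list lowered by 0.3 came out at a median of −0.29 and percentile 0, 1 of 38 lists with no shift fell outside the middle 95% of random lists, and the simulated depths were recovered at 100.01% and 100.02%. Simulated genes were drawn independently and with counting error only. The simulation therefore cannot show how often lists of genes that vary together fall outside that range. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.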

Results

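Mouse trophoblast stem cells, the precursors of the trophoblast lineages of the placenta, were placed in differentiation conditions for 2 days with or without doxycycline at 0.6 µg/ml, the drug that switched on an inducible Hand1 gene. Hand1 is a basic helix-loop-helix (bHLH) transcription factor that promotes the formation of trophoblast giant cells, the large polyploid cells that border the maternal tissue. RNA of each condition was sequenced as 1 library, named the no-dox library and the dox library in the text that follows. Values in RPKM, reads scaled by transcript length and library size, were listed for 23238 genes. Of these, 17092 were above 0 in the no-dox library and 16968 in the dox library. The spacing of the lowest values gave an estimated 20000000 counted reads for the no-dox library and 19200000 for the dox library. With 1 library per condition no difference has a replicate check, so genes are described as higher or lower in the dox library, and the intervals given cover counting error only.

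The comparison of the 2 libraries asked which transcripts differed in level with induced Hand1, and in particular whether Adgrg1 did. Hand1 was listed at 92.9 RPKM in the no-dox library and 396 RPKM in the dox library, 4.27-fold higher (log2 ratio 2.08). Adgrg1, which encodes an adhesion G protein-coupled receptor, was listed at 9.96 and 24.3 RPKM, 2.44-fold higher in the dox library (log2 ratio 1.21). Among the 8284 genes with a mean of at least 5 RPKM, Hand1 ranked 1 and Adgrg1 ranked 2 by the log2 ratio. Adgrg1 was looked up because the series title names it as a Hand1 target. Whether it was picked from these same 2 libraries is not known here, so its rank is not an independent check. Dusp6, a phosphatase that inactivates ERK and is itself induced by ERK signalling, was lower in the dox library, at 2.93 RPKM against 7.37 RPKM (log2 ratio −1.09).

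The 95% counting interval of the log2 ratio, taken without a pseudocount from estimated reads, ran from 2.04 to 2.15 for Hand1, from 1.16 to 1.41 for Adgrg1 and from −1.62 to −1.05 for Dusp6. Hand1 lies on chromosome 11 at 57828705 to 57832818 on the minus strand of GRCm38 (mm10), annotated as a protein-coding gene with 3 transcripts. Adgrg1 lies on chromosome 8 at 94974751 to 95014217 on the plus strand, a protein-coding gene with 16 transcripts. No other annotated gene overlapped either locus. Reads from the inducible Hand1 gene, if it was an introduced copy, were not told apart from reads of the Hand1 locus. The authors' deposited table gave a fold of 0.235 for Hand1 and 0.416 for Adgrg1, with the no-dox value in the numerator. The p-value for Adgrg1 in the authors' deposited table was 0.0791, and Hand1 was the 1 gene for which the authors' deposited table listed a p-value under 0.05.

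How many other genes differed by 2-fold depended on the scale. Of 11671 genes with at least 1 RPKM in one library, 11 were at least 2-fold higher and 9 at least 2-fold lower in the dox library, on the scale of log2(RPKM + 1), against 34 and 29 with a pseudocount of 0.1. The pseudocount of 1 left out 4 genes with a mean of at least 5 RPKM that passed 2-fold in plain RPKM and are not small RNAs: Wnt4 (2.07-fold higher), and Duoxa2, Gjb2 and Gm1673 (2.30-fold, 2.23-fold and 2.18-fold lower), named after their values were seen. Within the 11 and 9, apart from small nucleolar and small Cajal body RNAs, 5 genes were higher (Hand1, Adgrg1, Tbx21, Rgs5 and Snhg9) and 2 were lower (Dusp6 and Serpinb6c). Tbx21, a T-box transcription factor best known from T helper cells, was listed at 0.233 RPKM in the no-dox library and 3.76 RPKM in the dox library, an estimated 11.6 and 180 reads. Rgs5, a regulator of G protein signalling, was listed at 1.24 and 4.02 RPKM. Serpinb6c, a serine protease inhibitor, was lower in the dox library at 0.340 RPKM against 1.74 RPKM, and it belongs to a family of similar genes, for which reads shared between members were not tested. Snhg9, a small nucleolar RNA host gene, rested on an estimated 2.02 and 8.10 reads, its counting interval ran from −0.27 to 5.33, and it overlaps Rps2 and Snora78. Tbx21, Rgs5, Serpinb6c and Snhg9 had means under 5 RPKM and were named after their values were seen.

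The other 13 of the 20 genes past 2-fold were small nucleolar or Cajal body RNAs, 6 higher and 7 lower. They rested on a median of 6.17 estimated reads over both libraries together. Among them Snora28 was higher, at 9.56 RPKM against 4.22 RPKM, while Snora43 was lower, at 7.15 against 16.2 RPKM, and Snora33 was lower, at 4.48 against 10.7 RPKM. In simulated libraries of this depth, 14 of the 11015 genes left unchanged passed 2-fold by counting noise, 12 of them small nucleolar or Cajal body RNAs. The simulated small RNAs had GENCODE lengths, not the RefSeq lengths used for the observed ones, so their reads can differ. Across the 8284 genes with a mean of at least 5 RPKM, 99.4% of log2 ratios lay within 1.5-fold, with an SD of 0.15 across genes.

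**Figure D1:**
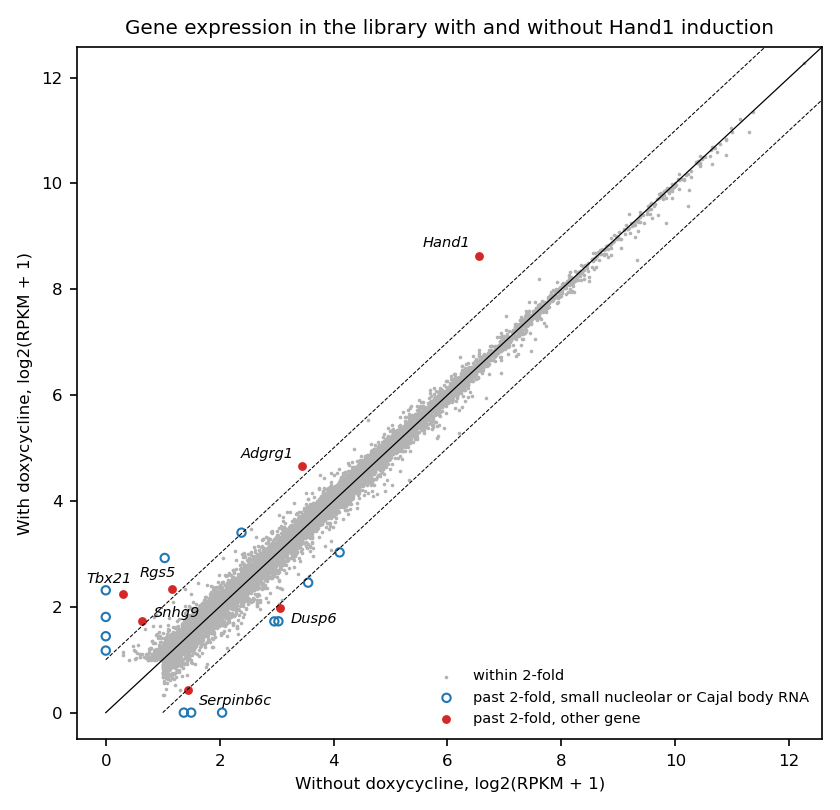
Each point is 1 of 11671 genes, with log2(RPKM + 1) in the library without doxycycline on the x axis and in the library with doxycycline on the y axis; the solid line marks equal values and the dashed lines 2-fold. Hand1 and Adgrg1 lie above the upper dashed line at log2 ratios of 2.08 and 1.21, Dusp6 lies below the lower line at −1.09, and open circles are the 13 small nucleolar or Cajal body RNAs past 2-fold.

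Genes of the trophoblast stem cell state were mostly lower in the dox library. Of 25 measured members of that list, 20 had a log2 ratio below 0, and the list median of −0.30 lay below all of 10000 random lists of genes with matched levels (percentile 0). None of the 25 reached 2-fold. Sox2, a transcription factor of the undifferentiated state, was listed at 14.4 RPKM in the no-dox library and 7.38 RPKM in the dox library (log2 ratio −0.88). Eomes, a T-box factor required for the trophoblast lineage, was listed at 72.4 and 51.7 RPKM (−0.48), Satb1 at 9.35 and 5.15 RPKM (−0.75) and Bmp4 at 2.68 and 1.63 RPKM (−0.48). Cdx2 and Elf5, which maintain trophoblast identity, both had a log2 ratio of −0.27. The members with the highest levels, Id2 and Rhox6, had log2 ratios of −0.30 and 0.02, and Tead4 had a ratio of 0.14. Apart from Id2, Rhox6 and Eomes, these members were picked after their values were seen.

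Lists of markers of differentiated trophoblast types also had medians below 0. For spongiotrophoblast and glycogen cells, 5 of 21 markers reached 1 RPKM, and their median log2 ratio was −0.52 (percentile 0), or −0.23 with no minimum level. Ascl2, a bHLH factor needed for spongiotrophoblast, was listed at 39.0 RPKM in the no-dox library and 20 RPKM in the dox library (−0.93), Phlda2 at 643 and 373 RPKM (−0.79), Gjb5 at 121 and 84.2 RPKM (−0.52) and Gjb3 at 207 and 163 RPKM (−0.34), while Flt1 had a log2 ratio of 0.08. Syncytiotrophoblast and labyrinth markers had a median of −0.15 over 16 members (percentile 0), with Gjb2 at 7.53 and 3.37 RPKM (−0.96), Gcm1, the factor that directs syncytiotrophoblast formation, at 1.59 and 0.901 RPKM (−0.44), and the abundant members Slc16a3 at −0.28 and Epcam at −0.10.

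Giant cell markers were mostly too low to compare at this time. Of 24 markers, 11 reached 1 RPKM, with a median log2 ratio of −0.21 (percentile 0.02), or −0.09 with no minimum; the abundant members Cdkn1c, a CDK inhibitor, and Tfap2c had log2 ratios of −0.47 and −0.34, Gata2 had −0.40 and Ada had 0.22. Tfap2c also belongs to the stem cell list. Prl3d1, which encodes placental lactogen I, a hormone of giant cells, was listed at 0.406 RPKM in the no-dox library and 0.778 RPKM in the dox library. In the prolactin family 25 of 26 genes stayed under 1 RPKM in both libraries, and the remaining member, Prl7a1, was listed at 1.36 and 1.47 RPKM. All 9 placental cathepsins and all 13 pregnancy-specific glycoproteins were under 1 RPKM in both libraries. None of the markers of these 3 differentiated types reached 2-fold on the log2(RPKM + 1) scale, and Gjb5, Flt1, Gjb2, Gcm1, Gata2, Ada and Prl3d1 were picked after their values were seen.

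**Figure D2:**
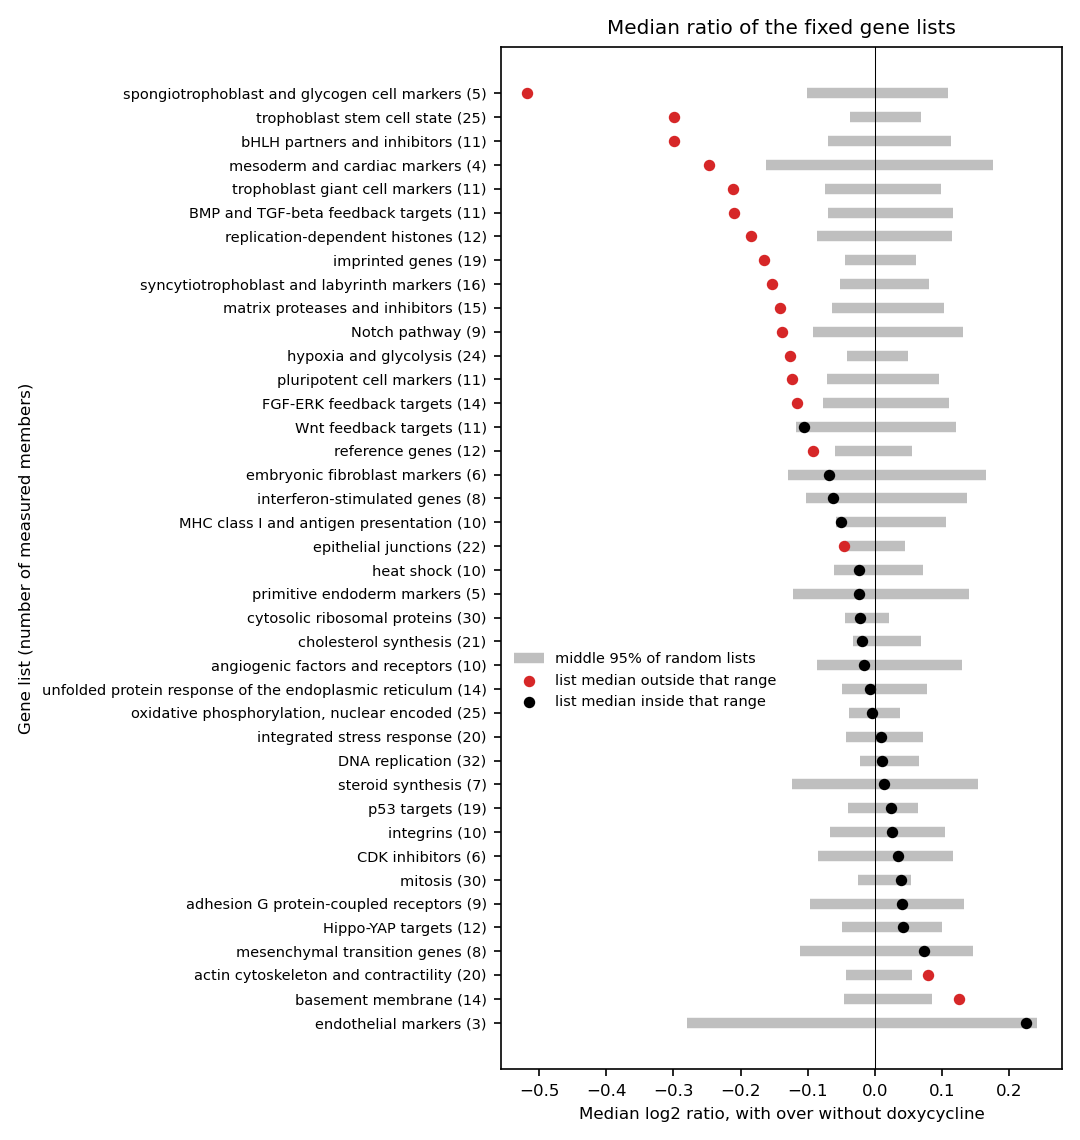
Median log2 ratio (dox over no-dox) of each gene list with at least 3 measured members, with the number of measured members in parentheses; grey bars span the middle 95% of 10000 random lists matched on level. In all, 16 lists lay below that range, led by spongiotrophoblast and glycogen cell markers at −0.52, and 2 lay above it, basement membrane at 0.12 and actin cytoskeleton at 0.08.

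Targets of several signalling pathways had medians below 0, with exceptions in each. The list of bHLH partners and inhibitors had a median log2 ratio of −0.30 over 11 members (percentile 0), or −0.15 with no minimum. Its Id genes, inhibitors that bind bHLH partners and are induced by BMP signalling, had log2 ratios of −0.44 (Id1), −0.30 (Id2) and −0.44 (Id3). The partners Tcf3 and Tcf12 had 0.01 and 0.18. They were the 2 of 11 measured members above 0, so the partner Tcf4, also on the list, was not measured above 0. Targets of BMP and TGF-beta had a median of −0.21 over 11 members (percentile 0), or −0.12 with no minimum, among them the inhibitory Smad6 at −0.28, Smad7 at −0.21 and the abundant Serpine1 at −0.20. Msx2, also a BMP target, went the other way, with 19.5 RPKM in the no-dox library and 30.7 RPKM in the dox library (0.63).

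FGF-ERK targets were split. Their median was −0.12 over 14 members (percentile 0.42). Beside Dusp6, Etv5 was lower in the dox library (−0.60), and the abundant members Myc and Ier3 had log2 ratios of −0.21 and −0.25. Egr1, at 0.785 and 2.12 RPKM (0.80), Fosl1 (0.44) and Fos (0.40) had log2 ratios above 0 but under the 2-fold rule. In plain RPKM, without the pseudocount, Egr1 was more than 2-fold higher. Notch pathway genes had a median of −0.14 over 9 members (percentile 0.43), which turned to 0.02 when members under 1 RPKM were kept; the most abundant, Rfng and Jag2, had log2 ratios of −0.18 and −0.11. The list of Wnt targets, which also holds Wnt ligands, had a median of −0.11 over 11 members. Its percentile was 3.61, against 37.4 without members under 5 RPKM, 2.47 with upper quartile scaling and 2.43 with the length trend removed. The ligands Wnt7b and Wnt6 had log2 ratios of −0.11 and 0.02. Dusp6 was the 1 member of these 5 lists past 2-fold on the log2(RPKM + 1) scale, and Id1, Id3, Tcf3, Tcf12, Smad6, Smad7, Msx2, Etv5, Egr1, Fosl1 and Fos were picked after their values were seen.

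**Figure D3:**
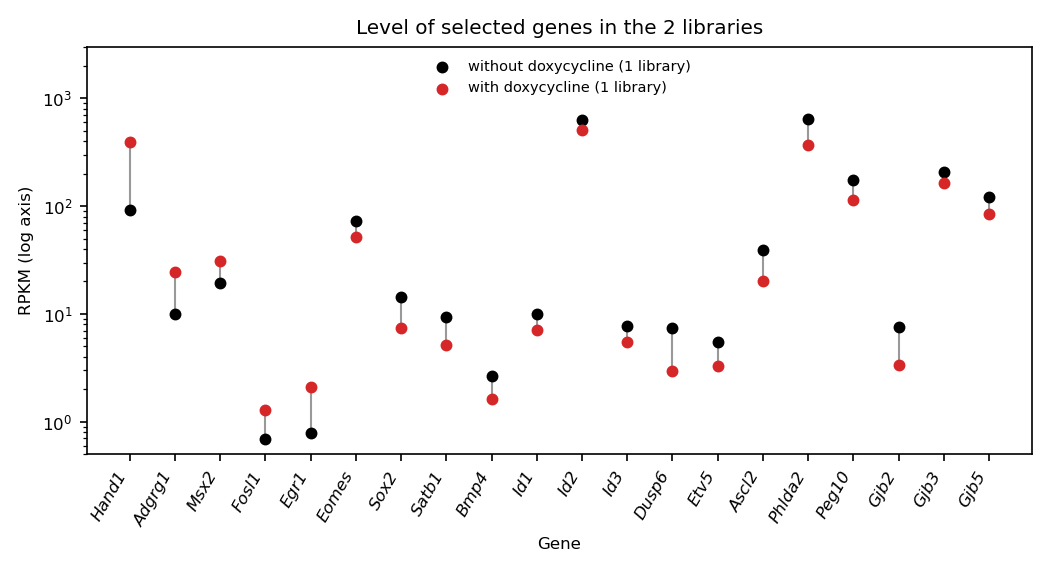
RPKM on a log axis of selected genes in the library without doxycycline (black) and the library with doxycycline (red), 1 library each, joined by a line per gene. Hand1 and Adgrg1 are higher in the dox library (396 against 92.9 RPKM and 24.3 against 9.96 RPKM), while Sox2, Eomes, Ascl2, Phlda2 and Dusp6 are lower.

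Lists of imprinted genes and of glucose metabolism had medians below 0, with small differences for most genes. Over 19 imprinted genes, 12 below 0 and 7 above it, the median log2 ratio was −0.17 (percentile 0), or −0.05 with no minimum. Igf2, a placental growth factor, was listed at 1206 RPKM in the no-dox library and 932 RPKM in the dox library (−0.37), and Peg10, required for placental development, at 177 and 113 RPKM (−0.64), while Sfmbt2 and Gab1 had log2 ratios of 0.15 and 0.11. Ascl2, Phlda2 and Cdkn1c also belong to this list. Of 24 genes of hypoxia and glycolysis, 22 had a log2 ratio below 0, with a median of −0.13 (percentile 0). The glucose transporter Slc2a3 was listed at 150 and 109 RPKM (−0.46), Ndrg1 at 147 and 106 RPKM (−0.47), and the abundant enzymes Pkm and Aldoa had log2 ratios of −0.17 and −0.22. Vegfa went the other way, at 0.29. None of these genes reached 2-fold, and apart from Igf2, Ascl2, Phlda2, Cdkn1c, Pkm and Aldoa they were picked after their values were seen.

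Genes of the basement membrane and of the actin cytoskeleton were the 2 lists with medians above the random range. Over 14 basement membrane genes the median log2 ratio was 0.12 (percentile 99.9, and 92.7 with no minimum), with the laminin chain Lamb1 at 0.28, the heparan sulfate proteoglycan Hspg2 at 0.25, the abundant Sparc at 0.22 and Col4a1 at −0.02. Over 20 actin cytoskeleton and contractility genes the median was 0.08 (percentile 99.7), with the non-muscle myosin Myh10 at 0.34, the crosslinker Flna at 0.33, and the abundant Tagln2 and Tpm1 at −0.05 and 0.03. Log2 ratios were higher for longer transcripts (Spearman 0.26 across 8012 genes, which are not independent), and against random lists matched on length as well the percentiles were 95.6 for the basement membrane and 99.6 for the actin cytoskeleton. With the length trend removed from the ratios they were 58.4 and 94.2.

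Matrix proteases and their inhibitors had a median of −0.14 over 15 members, 12 below 0 and 3 above it (percentile 0.07), with the abundant Htra1 at −0.35 and Serpine2 at −0.11. Integrins had a median of 0.02 over 10 members (percentile 56.3), although Itga3 was listed at 39.4 RPKM in the no-dox library and 52.7 RPKM in the dox library (0.41). The abundant integrins Itgb1 and Itgb5 had log2 ratios of −0.07 and 0.13. Epithelial junction and keratin genes had a median of −0.05 over 22 members (percentile 2.08, and 11.8 without members under 5 RPKM), with the keratins Krt18 and Krt8 at −0.19 and −0.24. Genes of the mesenchymal transition had a median of 0.07 over 8 members (percentile 80.3). None of these genes reached 2-fold on the log2(RPKM + 1) scale, and Lamb1, Hspg2, Myh10, Flna and Itga3 were picked after their values were seen.

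Within the adhesion G protein-coupled receptors Adgrg1 stood alone. The other 8 measured members of the family had log2 ratios from −0.21 (Adgrl2) to 0.29 (Celsr1, picked after its value was seen), and the list median of 0.04 lay at percentile 65.9. Adgrl1 was listed at 16.1 RPKM in both libraries.

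Mitosis and DNA replication genes did not stand apart from random lists. Mitosis genes had a median log2 ratio of 0.04 over 30 members (percentile 88.7), with Top2a at 182 RPKM in the no-dox library and 189 RPKM in the dox library and Ube2c at 236 and 237 RPKM. DNA replication genes had a median of 0.01 over 32 members (percentile 31.9), with Rrm2 at 152 RPKM in both libraries and Pcna at 151 and 154 RPKM. CDK inhibitors had a median of 0.03 over 6 members (percentile 64.7), with Cdkn1a at 75.6 and 78.8 RPKM. Replication-dependent histones had a median of −0.18 over 12 members (percentile 0.04), but with members under 5 RPKM left out the median turned to 0.16 and the percentile to 98.8, above the random range.

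Stress and housekeeping lists mostly lay inside the random range. The integrated stress response, which antibiotics that act on mitochondria can induce, had a median log2 ratio of 0.01 over 20 members (percentile 41.4), with Atf4 at −0.01, Phgdh at 0.01 and Chac1, picked after its value was seen, at 0.67. The random range also held the unfolded protein response (median −0.01), p53 targets (0.02), heat shock genes (−0.02), interferon-stimulated genes (−0.06), antigen presentation genes (−0.05), cytosolic ribosomal proteins (−0.02), nuclear-encoded oxidative phosphorylation genes (−0.01), cholesterol synthesis (−0.02), steroid synthesis (0.01), angiogenic factors (−0.02) and Hippo-YAP targets (0.04). The 12 reference genes, 8 below 0 and 4 above it, had a median of −0.09 (percentile 0.22), with Actb at −0.09 and Ubc at 0.06. Under at least 1 other scaling the sign of the median turned for 7 lists, whose medians were at most 0.02 in size after rounding: DNA replication, integrins, steroid synthesis, the integrated stress response, the unfolded protein response, p53 targets and oxidative phosphorylation. No mitochondrially encoded gene was found among the listed genes under its symbol in the fixed list, so these genes were not analysed here.

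Pluripotent cell markers had a median log2 ratio of −0.12 over 11 members (percentile 0.18), with the abundant Dnmt3b and Utf1 at −0.05 and −0.03. Mesoderm and cardiac markers had a median of −0.25 over 4 members (percentile 0.61), of which Eomes is also a trophoblast stem cell gene, but with no minimum the median was −0.03 and the percentile 18.6. Fibroblast markers (6 members, median −0.07, percentile 10.2), primitive endoderm markers (5 members, −0.02, percentile 29.1) and endothelial markers (3 members, 0.23, percentile 96.9) lay inside the random range. The endothelial percentile was 97.8 with random lists matched on length and 97.9 with the length trend removed, both above that range. With no minimum it was 77.4. Of 14 blood markers, Cd68 at 8.39 and 6.58 RPKM and Csf1r at 2.57 and 2.17 RPKM reached 1 RPKM, and every globin gene of that list was listed at 0 in both libraries. Xist was listed at 75.4 RPKM in the no-dox library and 92.6 RPKM in the dox library, and the 4 Y-linked genes of the same list were under 1 RPKM in both. Percentiles describe these 2 libraries, since genes are not replicates. If genes varied independently, 1 list of the 40 would be expected on each side. Genes of a list can vary together and some lists share members, so that number is too low a yardstick.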

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

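The settings added after the data were seen were trimmed mean scaling, removal of the length or GC trend, the interval that excludes no difference and leaving out small RNAs. Hand1 and Adgrg1 stayed past 2-fold under each scaling, pseudocount and trend removal run, and in total 364 recomputed values, and 28 for single named genes, stayed within 1.5 times the main count, the counting interval of the gene or the range from resampling the members of the list. That range is wide for small lists, so such values include changes of sign and of size. Of the 16 lists below the middle 95% of random lists, 16 stayed there by column total, 15 by median of ratios, upper quartile or trimmed mean, 16 with a pseudocount of 0.1, 14 with no minimum and 13 of 15 with a minimum of 5 RPKM. Of the 2 lists above, 2 stayed under each scaling, the pseudocount and the minimum of 5 RPKM, 1 with no minimum and 0 with the length trend removed. The cause was not tested for the changes that follow unless a construction is named.

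Counts of higher genes (11) moved: 34 with a pseudocount of 0.1, 4 with a minimum of 5 RPKM, 50 at 1.5-fold, 2 at 4-fold, 5 with an interval that excludes no difference, 4 with an interval bound of 2-fold and 5 without small RNAs. Counts of lower genes (9) were 29, 5, 64 and 1 under the first 4 of these settings, 2 with an interval bound of 2-fold and 2 without small RNAs.

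Medians of 2 lists outside the random range turned sign: Notch pathway went to 0.0205 with no minimum and replication-dependent histones to 0.157 with a minimum of 5 RPKM (percentile 98.8), each over other members. With no minimum the giant cell median went to −0.0927 and the endothelial median to 0.0175. Within the resampling range, spongiotrophoblast went to −0.230, imprinted genes to −0.0478 and mesoderm to −0.0332 with no minimum. Wnt targets went to −0.00106 with a minimum of 5 RPKM, also within it. The pseudocount of 1 presses ratios of members under 1 RPKM in both libraries toward 0. Part of the pull of medians with no minimum is thus built in. Against random lists of matched level, percentiles with no minimum were 0.08 (giant cell), 0 (spongiotrophoblast), 0.82 (imprinted), 18.6 (mesoderm), 73.0 (Notch) and 77.4 (endothelial). Under at least 1 other scaling 7 lists with medians near 0 changed sign. Scaling by median of ratios, upper quartile and trimmed mean gave, in that order, −0.0437, −0.0522 and −0.0448 for cholesterol synthesis, 0.000367, −0.00784 and −0.000653 for p53 targets, −0.0473, −0.0558 and −0.0483 for ribosomal proteins, −0.0292, −0.0377 and −0.0302 for oxidative phosphorylation and −0.116, −0.124 and −0.117 for reference genes. The upper quartile also gave −0.017 for DNA replication and −0.056 for primitive endoderm. A scaling moves nearly all genes by a similar amount. The median of all genes shifted by −0.0220 (median of ratios), −0.0298 (upper quartile), −0.0230 (trimmed mean) and 0.00746 (column total). Changes of about that size under a scaling are thus built in and not particular to a list. With the length trend removed, ribosomal proteins went to 0.00858, oxidative phosphorylation to 0.0177 and steroid synthesis to 0.0481.

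Depth-matched thinning was not run, because the values are not counts and the estimated depths differ by 3.79%. No paired analysis was possible because each group holds 1 library. Depth limits the small nucleolar and Cajal body RNAs most, whose short transcripts collected at most 45.0 estimated reads among those past 2-fold.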

Other observations

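The genes named in the next 2 paragraphs were chosen after their values were seen, and so was the test of the deposited p-values; the tests of length, GC content and counting noise were set before their results were seen.

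The larger differences at well-measured levels were mostly lower values in the dox library. Of all genes, members of the fixed lists included, with a mean of at least 5 RPKM that are not small nucleolar or Cajal body RNAs, 25 were at least 1.5-fold lower and 11 at least 1.5-fold higher with a counting interval that excluded no difference. Fgfbp1, a secreted carrier of FGF ligands, was listed at 72.5 RPKM in the no-dox library and 37.9 RPKM in the dox library (log2 ratio −0.92), and the FGF receptor Fgfr4 had a log2 ratio of −0.63. The metallothioneins Mt2 and Mt1, which bind zinc and copper, were listed at 1189 and 760 RPKM (−0.65) and at 918 and 610 RPKM (−0.59). Carbonic anhydrase Car2 was listed at 101 and 60.2 RPKM (−0.74), the transcription factor Gata1 at 31.7 and 18.7 RPKM (−0.73), and Plac1, an X-linked gene of the placenta, at 55.6 and 35.4 RPKM (−0.64). Duoxa2, the maturation factor of the dual oxidase Duox2, was listed at 7.27 and 3.16 RPKM (−0.99), beside Duox2 itself, a member of the stem cell list, at −0.42.

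Among the higher genes, Wnt4, a secreted Wnt ligand, was listed at 4.85 RPKM in the no-dox library and 10.1 RPKM in the dox library (log2 ratio 0.92). Gstm5, a glutathione S-transferase, was listed at 23.4 and 45.3 RPKM (0.92). Klhl13, a substrate adaptor of a cullin 3 ubiquitin ligase that acts in mitosis, was listed at 195 and 294 RPKM (0.59), and Ndst1, an enzyme of heparan sulfate synthesis, at 10.4 and 16.7 RPKM (0.63).

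A first pattern was that 16 of 40 fixed lists, with 197 distinct members, had medians below the middle 95% of random lists. If genes varied independently, 1 such list would be expected. Genes of a list can vary together between any 2 cultures, and some lists share members. More than 1 list can therefore fall below with no effect of Hand1. Length bias is argued against, since 16 of the 16 lists stayed below with random lists matched on transcript length, and so is GC bias, since 15 of the 16 stayed below when matched on GC content, and the ratio had no trend with GC content (Spearman −0.01 across 8012 genes). Counting noise of weak members is argued against as the cause of most of it, since 13 of the 15 lists that kept 3 members stayed below without members under 5 RPKM. The reference gene list is 1 of the 16. Medians near its −0.09 may thus hold a difference between the libraries that no gene group explains. It shares Gapdh and Pgk1 with the glycolysis list, and all eligible genes had a median of 0.02. The stem cell list (−0.30) and the spongiotrophoblast list (−0.52, or −0.23 with no minimum) lie further out. Ranges from resampling the members were −0.42 to −0.12 (stem cell), −0.93 to 0.08 (spongiotrophoblast) and −0.11 to 0.02 (reference). The spongiotrophoblast and reference ranges covered 0, as did those of the FGF-ERK, BMP and TGF-beta, Notch, epithelial junction, imprinted, mesoderm and histone lists. Those of the rest of the 16 lay below 0. Induced Hand1, doxycycline itself and a difference between 2 cultures all stay open, because each condition has 1 library and no library with doxycycline but without induced Hand1 was analysed here.

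The second pattern was the pair of lists with medians above the middle 95% of random lists, basement membrane and actin cytoskeleton. With members resampled, the middle 95% of medians ran from −0.05 to 0.21 and from −0.01 to 0.19, and both ranges covered 0. A trend of the ratio with transcript length is a candidate explanation for part of it: 1 of the 2 lists, the actin cytoskeleton, stayed above when random lists were matched on length, and neither did (0 of 2) when the length trend was removed, which put the basement membrane at percentile 58.4 and the actin cytoskeleton at 94.2. With genes ordered by length and cut into 10 equal parts, the median log2 ratio was 0.00 in the part with the shortest transcripts and 0.11 in that with the longest. A trend of the ratio with transcript GC content is argued against, since 2 of the 2 lists stayed above when matched on it. Whether the actin genes differ because of induced Hand1 stays open.

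The third pattern was the p-value of 0.0791 that the authors' deposited table gives for Adgrg1, although its value differed by 2.44-fold on an estimated 715 and 1680 reads. A candidate explanation is that the deposited p-values treat RPKM as if they were read counts. A negative binomial exact test with a dispersion of 0.05 on slightly rescaled RPKM, rounded to whole numbers, met the deposited p within 0.0015 for 96.1% of 11445 genes, against 69.4% with a dispersion of 0.1 and 79.6% without rescaling, which is short of the 90% asked for. For Adgrg1 it met the deposited p. The dispersion and the scale were picked by trial on the same deposited p-values, so the match leans on them, and both p-values compare 2 libraries, not 2 conditions. Of 23238 listed genes, 19750 had a deposited p at its upper limit, which near-equal values can meet whatever the dispersion. The shares met therefore include genes that cannot tell the settings apart. The match among the other genes was not computed.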
